A study of Homo sapiens with 4 samples.

How the data were processed

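Poly(A) RNA was sequenced from NCI-H929 cells, an established human multiple myeloma line that here expressed Cas9, the nuclease that cuts DNA where a guide RNA directs it. Per the labels' protocols, cells received either a control construct or a doxycycline-inducible BCL7A knockout (KO) construct, and were selected with puromycin for 3 days. Doxycycline at 0.5 ug/ml was then present during 24 h before RNA was isolated and made into strand-specific libraries. The titles and genotype labels call the controls wild type, which does not match a control construct, and nothing here settles which is right. The 4 libraries form 2 groups of 2, BCL7A KO and control. The labels give no batch or date, and nothing in them says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

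The authors deposited 1 table of estimated counts per gene, made with Salmon 0.12 on GRCh38 per the submitters' processing notes. All deposited values were whole numbers and were used as they stood. The annotation and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes are reported as uncertain. All 56809 gene names of the table are gene names of GENCODE release 29, and coordinates were taken from that annotation (GRCh38). A further 92 rows name ERCC spike-in sequences, which held at most 5 counts in a library and were left out of library sizes and tests.

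Genes with low counts were removed with filterByExpr, which left 17885 tested genes. Libraries were scaled with TMM factors (0.909 and 0.906 in the KO libraries, 1.10 in both control libraries), and the groups were compared with edgeR 4.0.16 (estimateDisp, glmQLFit with robust=TRUE, glmQLFTest) without covariates. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. A log2 fold change is KO over control, and its standard error (SE) is its absolute value over the square root of the test's F statistic. Rose and fell mean higher and lower in the KO than in the control libraries, and do not say in which group the level changed. Levels are CPM, counts scaled to library size with the TMM factors, given as mean ± SD with n = 2 per group. Where both libraries of a group had 0 counts, the fold is a bound set at 3 counts over the group, which is 0.0416 CPM in the KO group and 0.0723 CPM in the control group. With 1 to 3 counts in a group, the ratio is given with an exact 95% Clopper-Pearson counting interval. These bounds and intervals cover counting error only.

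Before the data were examined, 34 gene lists were fixed, with 984 entries, of which 983 matched a row, 27 of them through another symbol of the same Ensembl gene. Each list with at least 5 tested members was compared with the other genes by camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 34 lists, and again with the correlation estimated for each list. The rule for named genes was also fixed then. It takes BCL7A, BCL7B, BCL7C, IRF4 and MYC. Among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups, it takes the 8 with the highest and the 8 with the lowest log2 fold change, and the 5 with the smallest p in each direction. It also takes up to 4 members of each list described, by smallest p. Genes named outside this rule are marked as chosen after their values were seen.

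The alternatives fixed beforehand were RLE and upper-quartile factors, no filter and a stricter filter on low counts (a mean count of at least 10 and at least 1 CPM in 2 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, no robust shrinkage, a threshold of 0.01, an estimated inter-gene correlation and the rotation test fry. Because the KO libraries were deeper, a fit with their counts thinned at random to the mean depth of the control libraries was added after the data were seen. Upper-quartile factors moved the median log2 fold change of all genes by -0.13 against TMM, so small changes are relative to the scaling.

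Blocks of neighbouring genes were examined after the data were seen, over 8787 protein-coding autosomal genes with a mean of at least 10 CPM. The median log2 fold change was taken in 211 consecutive windows of 40 genes, minus the median of all these genes, and a window was called outside chance when it passed the 95% limit of the most extreme window in 1000 shuffles of gene order. Contrasts between replicates used log2 of CPM plus 0.5. A correction for GC content and transcript length subtracted the running median of the log2 fold change over each in turn, with both taken from the longest transcript.

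The scripts were tested on simulated data. With counts drawn for the genes of this comparison at its library sizes (17158 genes tested), the edgeR fit recovered 14 of 50 genes changed 1.2-fold, 40 of 50 changed 1.5-fold, 42 of 50 changed 2-fold and all 50 changed 4-fold, and it called 10 unchanged genes. Camera called the 1 shifted list and 0 of 20 unshifted lists. Simulated genes were drawn independently and nearly all were unchanged, so camera was not tested under correlated genes or widespread change. The window scan found 30 of 30 shifted windows among 200 simulated windows and 0 others. Analyses ran in R 4.3.3 and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9.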

Results

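Gene expression was measured by poly(A) RNA-seq in NCI-H929 multiple myeloma cells 24 h after doxycycline was added, in 2 libraries from cells carrying an inducible BCL7A KO construct and 2 from control cells. The protocol gives the control cells a control construct, whereas the sample titles call them wild type; untransduced controls would leave the effects of transduction and selection mixed with those of the KO. BCL7A is a subunit of BAF (SWI/SNF) chromatin remodelling complexes. Gene counts summed to 38671744 and 40799624 in the KO libraries and to 17567202 and 20153596 in the control libraries, so depth differed along with the group. More genes had at least 1 count in the control libraries (25792 and 26466) than in the deeper KO libraries (24212 and 24293).

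The 2 libraries of each group differed by more than sampling noise (chi-square per degree of freedom 1.79 over 16159 genes in the KO group and 2.43 over 16778 genes in the control group), so they were counted separately. Even so, the biological coefficient of variation was only 2.32%. Across genes, log2 CPM correlated at r = 0.999 between the KO libraries, at 0.996 between the control libraries and at 0.931 to 0.932 between groups; genes are not independent replicates. The first principal component, which separated the groups, held 94.3% of the variance.

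The comparison of the KO with the control libraries asks how loss of BCL7A changes transcription in myeloma cells, in particular the program of IRF4, the plasma cell transcription factor on which myeloma cells depend. BCL7A mRNA (chromosome 12, 122019422 to 122062044, plus strand) was 1.25 ± 0.0842 CPM in the KO libraries and 44.3 ± 1.94 CPM in the control libraries, 35.4-fold lower (log2 fold change -5.15, SE 0.11, adjusted p = 3.51e-25). Low BCL7A mRNA in both KO libraries goes with their label, although a cut by Cas9 need not lower the mRNA of its target. BCL7A is also only 1 of 478 genes at least 10-fold lower there, so its level does not separate a knockout from a different culture. Cell cycle, proteasome, respiratory chain, interferon and plasma cell genes were higher in the KO libraries, while mature B cell genes, NF-kB targets and replication-dependent histone genes were lower. These are calls on lists by camera with a preset inter-gene correlation, and each was lost when the correlation was estimated (smallest adjusted p = 0.155). Over all tested genes, 478 were at least 10-fold higher in the control libraries and 9 were at least 10-fold higher in the KO libraries.

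IRF4 itself (chromosome 6, 391739 to 411447) was 1724 ± 11.8 CPM in the KO and 1481 ± 8.91 CPM in the control libraries (log2 fold change 0.22, SE 0.02, adjusted p = 3.39e-10). MYC (chromosome 8, 127735434 to 127741434), an oncogenic transcription factor that is a direct IRF4 target in myeloma, was 497 ± 0.801 CPM against 556 ± 5.20 CPM (log2 fold change -0.16, SE 0.02, adjusted p = 1.24e-06). Both changes are close in size to the shift between scalings. Over the alternatives, IRF4 ranged from 0.09 to 0.30 and MYC from -0.29 to -0.08, each past the threshold throughout. The paralogs of BCL7A were also lower in the KO libraries. BCL7B (chromosome 7) was 26.3 ± 2.02 against 32.3 ± 0.730 CPM (log2 fold change -0.30, SE 0.07, adjusted p = 1.93e-04), a call that DESeq2 did not make (log2 fold change -0.26, adjusted p = 0.0685, the largest over the alternatives). BCL7C (chromosome 16) was 8.13 ± 0.626 against 12.5 ± 1.77 CPM (log2 fold change -0.62, SE 0.12, adjusted p = 3.69e-05).

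**Figure D1:**
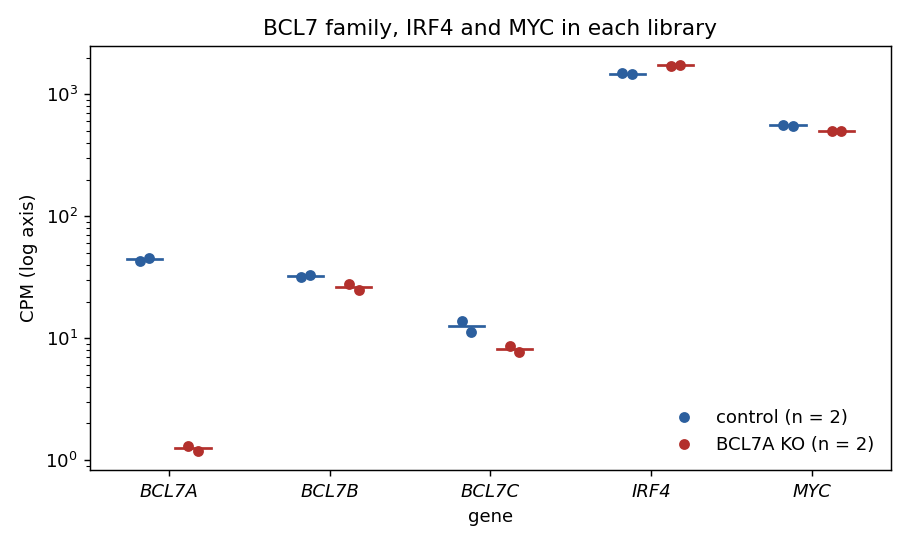
CPM on a log axis of BCL7A, its paralogs BCL7B and BCL7C, IRF4 and MYC; each point is 1 library and each line a group mean (control blue, KO red, n = 2 each). BCL7A lies at 1.25 CPM in the KO and 44.3 CPM in the control group, while IRF4 and MYC lie close together in both.

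Of 17885 tested genes, 13629 passed the threshold, 6506 higher and 7123 lower in the KO libraries. Of these, 5891 changed at least 2-fold, 1693 upward and 4198 downward. The 5 genes with the smallest p among those that rose began with MAN1A1, a mannosidase of N-glycan processing (2139 ± 27.5 against 504 ± 6.25 CPM). The others were MX1, an interferon-induced antiviral GTPase (898 ± 1.27 against 230 ± 2.33 CPM), and CCND2, which encodes cyclin D2 (195 ± 3.62 against 15.3 ± 1.16 CPM). They were followed by CCNB1, which encodes cyclin B1 (262 ± 5.53 against 34.9 ± 0.721 CPM), and MAP1B, which encodes a microtubule-associated protein (854 ± 14.2 against 226 ± 2.90 CPM). By size, among genes with a mean of at least 1 CPM and no overlap between groups, the processed pseudogene DCAF13P3 rose most, from 0.209 ± 0.15 to 18.1 ± 0.25 CPM (log2 fold change 6.36, SE 0.22), a value that reads shared with its parent gene could change. Next came A2M, which encodes a protease inhibitor, with 3 counts in the control group and a ratio of 44.9 (95% counting interval 15.2 to 219). GAS2L3 (log2 fold change 5.24, SE 0.31) was next, ahead of GAL, which encodes the neuropeptide galanin and also had 3 counts in the control group (ratio 28.4, interval 9.54 to 139). The tubulin gene TUBB2B (4.69, SE 0.29), TEX15 (4.61, SE 0.26) and the mitotic regulator PIMREG (4.59, SE 0.19) followed. AC008012.1 (4.46, SE 0.29) overlaps CCND2 on the same strand, so their counts cannot be fully separated.

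The 8 genes that fell furthest under the same limits had 0 counts in both KO libraries. The immunoglobulin delta constant gene IGHD (chromosome 14, 105836765 to 105845678, minus strand) was 4682 ± 29.2 CPM in the control libraries, at least 112470-fold higher than in the KO libraries. The index used for counting is not given, so the assignment of reads among heavy chain constant genes is uncertain. The heavy chain variable gene IGHV3-7 was 175 ± 5.51 CPM there, at least 4200-fold higher, and reads of variable genes can be shared among near-identical copies. PRSS21, a serine protease gene, EPCAM, an epithelial adhesion gene, and PLCB2, a phospholipase C gene, were 53.2 ± 1.93, 52.9 ± 2.12 and 44.8 ± 2.64 CPM in the control libraries, each at least 1076-fold higher. The non-coding genes LINC01287, LINC00899 and AFAP1-AS1 were 41.5 ± 0.685, 34.8 ± 0.470 and 32.7 ± 2.96 CPM. AFAP1-AS1 is antisense to AFAP1, and its counts are uncertain without a stated strand setting. Genes with the smallest p among those that fell were IGHD, MTCO1P12, LCP1, ETS1 and CD74. LCP1, which encodes the actin-bundling protein L-plastin, was 6.18 ± 0.163 against 322 ± 7.17 CPM. The transcription factor gene ETS1 was 9.04 ± 0.303 against 314 ± 0.0529 CPM. CD74, the invariant chain of MHC class II, was 1.41 ± 0.342 against 266 ± 4.24 CPM. MTCO1P12, a nuclear copy of the mitochondrial gene MT-CO1 with 98.7% identity over 1542 bases, was 4.28 ± 0.154 CPM in the KO and 1256 ± 41.3 CPM in the control libraries. Its counts can include reads of MT-CO1. MT-CO1 itself was 21081 ± 209 CPM in the KO and 16442 ± 66.7 CPM in the control libraries. Reads shared in proportion to MT-CO1 would therefore not lower MTCO1P12 in the KO libraries. Sharing that differs between the groups was not tested.

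**Figure D2:**
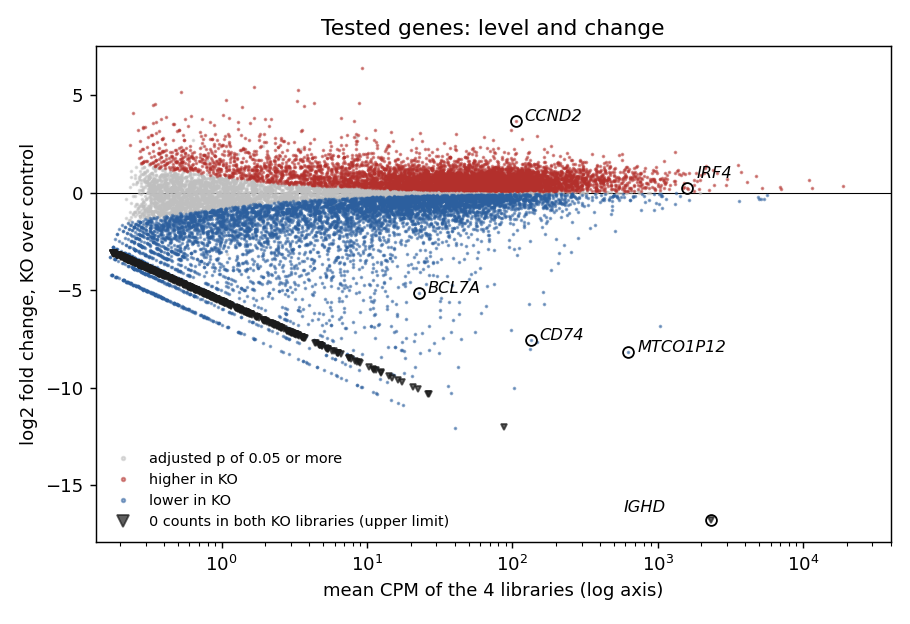
Log2 fold change (KO over control) of each tested gene against its mean CPM over the 4 libraries on a log axis; red and blue points passed the threshold, grey did not. Black triangles mark genes with 0 counts in both KO libraries, drawn at the upper limit that 3 counts allow. Differences reach much further below 0 than above it, with IGHD at the bottom.

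The largest differences between the groups were one-sided, with far more genes nearly absent from the KO than from the control libraries. The 478 and 9 genes that differed at least 10-fold had at least 5 CPM in the higher group. Of genes with at least 1 CPM in the control group, 237 had 0 counts in both KO libraries, 74 of them among the 478, and 1 gene showed the opposite. Changes also followed position along the chromosomes. Of 211 windows of 40 neighbouring genes, 23 had a median outside the limit of 0.48 that shuffled gene order gave, 12 above and 11 below. The contrasts between replicates had their own, narrower limits. There, 1 window lay outside 0.0405 in the KO group and 0 lay outside 0.0666 in the control group. On chromosome 5, 84.0% of 412 genes lay above the overall median and the chromosome's median log2 fold change was 0.74. On chromosome 7, only 26.0% of 416 genes did, with a median of -0.19. The lowest window spanned chromosome 13 from 60396457 to 112588205, with a median of -0.62, where the median of all these genes was 0.20.

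**Figure D3:**
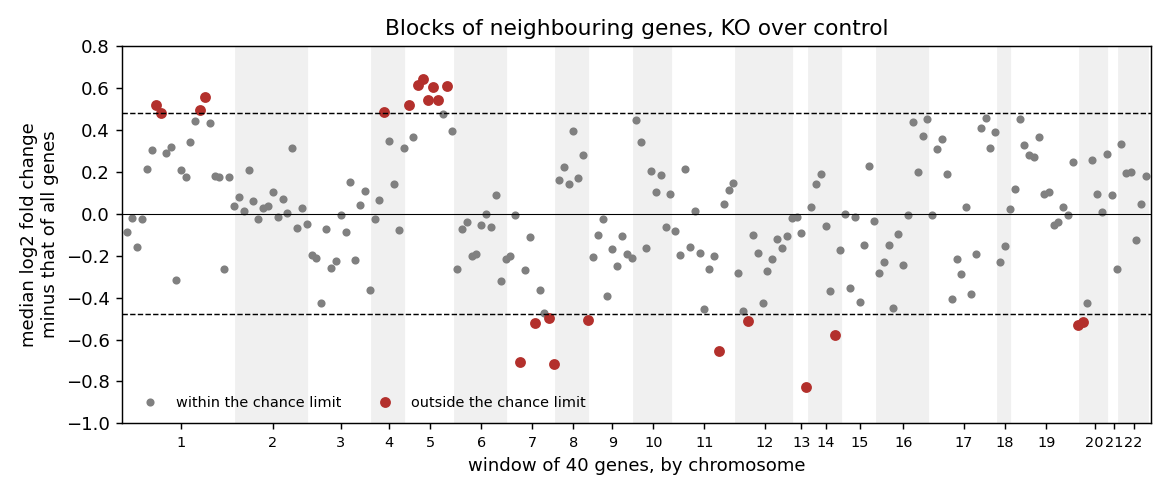
Median log2 fold change (KO over control) of 211 consecutive windows of 40 protein-coding genes, minus the median of all these genes, in order along chromosomes 1 to 22; dashed lines mark the limit of 0.48 from shuffled gene order. The 23 red windows lie outside it, with a run of high windows on chromosome 5 and low windows on chromosome 7.

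Of the 34 lists, 20 differed from the other genes by camera, 14 upward and 6 downward. The median log2 fold change was -0.06 over all tested genes. It was 0.20 over the 8787 protein-coding autosomal genes with a mean of at least 10 CPM. No list was compared with genes of matched expression, so small upward medians of highly expressed lists are uncertain. When the inter-gene correlation was estimated, camera called 0 lists, with a smallest adjusted p of 0.155, and 10 lists had an unadjusted p under 0.05. Calls were lost also where the estimate lay below the preset, as for heat shock genes (-0.046), so their loss does not by itself show strong correlation. The rotation test fry tests each list on its own. With 13629 of the 17885 tested genes past the threshold, such a test can call a list that does not differ from other genes. Fry called 30 lists, the 20 that camera called in the main fit and 10 more. The 10 were the BAF subunits, BCL2 family, immediate early, hypoxia, adhesion, fatty acid synthesis and mitochondrially encoded lists and the epithelial, myeloid and erythroid markers (largest adjusted p = 0.0118). Counts of members past the threshold were equal when adjusted over the list alone in 31 of the 34 lists, and differed by 1 gene in the other 3. Those were the MYC targets, where 9 rather than 8 fell, the immediate early genes, where 12 rather than 11 fell, and the BAF subunits, where 12 rather than 11 rose.

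Cell division genes rose together. Of 55 genes of the G2 and M phases, 52 rose and 2 fell, with a median log2 fold change of 1.09 (adjusted p = 2.55e-21; adjusted p = 0.155 with an estimated correlation). CCNB1 rose 7.49-fold, and CDC20, an activator of the anaphase-promoting complex, was 128 ± 2.91 against 19.8 ± 1.64 CPM. TUBB4B, a tubulin gene, was 393 ± 1.14 against 122 ± 2.04 CPM, and TPX2, a spindle assembly factor gene, 298 ± 2.51 against 105 ± 1.55 CPM. Among 47 S phase genes, 31 rose and 9 fell (median 0.43, adjusted p = 0.00387; adjusted p = 0.399 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, was 302 ± 4.14 against 78.5 ± 2.12 CPM. By contrast, CDCA7 had 0 counts in both KO libraries and 22.5 ± 1.38 CPM in control, at least 541-fold higher there. Replication-dependent histone genes went the other way, with 0 of 18 higher and 14 lower (median -1.37, adjusted p = 1.87e-04; adjusted p = 0.155 with an estimated correlation). HIST2H2BE was 44.4 ± 1.73 against 107 ± 3.85 CPM and HIST1H2BD 16.3 ± 0.469 against 53.5 ± 0.0129 CPM. These mRNAs mostly lack poly(A) tails, and their family members are near-identical, so their levels in a poly(A) library are uncertain.

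Genes of protein turnover and energy metabolism were mostly higher. All 34 proteasome genes rose (median 0.79, adjusted p = 1.92e-18; adjusted p = 0.155 with an estimated correlation). PSMB4 was 602 ± 4.99 against 266 ± 4.47 CPM and PSMD12 137 ± 0.749 against 50.9 ± 0.168 CPM. Of 77 nuclear-encoded genes of oxidative phosphorylation, 73 rose and 2 fell (median 0.72, adjusted p = 5.61e-15; adjusted p = 0.188 with an estimated correlation). Among them were SDHA of complex II (log2 fold change 1.17, SE 0.03) and ATP5F1A of ATP synthase (1.05, SE 0.02). The 13 mitochondrially encoded genes did not pass as a list (9 rose, 4 fell, adjusted p = 0.103), but did by fry, and by camera with no filter and with limma-voom (adjusted p = 0.00682 and 0.0433). Of 23 glycolysis genes, 15 rose and 7 fell (adjusted p = 4.31e-07; adjusted p = 0.155 with an estimated correlation). Their median was 0.48 but their mean -0.0028. LDHA, PKM, PGAM1 and ENO1 all rose, LDHA to 1660 ± 9.58 from 542 ± 2.36 CPM. Heat shock genes rose in 15 of 18 cases (median 0.84, adjusted p = 2.01e-08; adjusted p = 0.155 with an estimated correlation). The chaperone gene HSPA8 was 2975 ± 11.8 against 1251 ± 13.8 CPM. In the unfolded protein response, 22 of 30 rose and 5 fell (median 0.36, adjusted p = 1.70e-05; adjusted p = 0.155 with an estimated correlation). Its chaperone gene CANX and transcription factor gene XBP1 had log2 fold changes of 1.02 and 0.90. The integrated stress response (20 of 30 rose, 6 fell, median 0.40, adjusted p = 0.0109; adjusted p = 0.222 with an estimated correlation) no longer passed with upper-quartile factors or with a stricter filter. TRIB3 of this list fell to 55.0 ± 0.308 from 186 ± 7.56 CPM.

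Plasma cell genes and mature B cell genes moved apart. Of 26 plasma cell identity genes, 22 rose and 4 fell (median 0.71, mean 0.21, adjusted p = 1.79e-10; adjusted p = 0.155 with an estimated correlation). MZB1, a chaperone of immunoglobulin assembly, was 652 ± 2.93 against 246 ± 0.825 CPM. The surface proteoglycan gene SDC1 (CD138) was 665 ± 1.73 against 274 ± 4.11 CPM, and JCHAIN 5031 ± 21.5 against 2452 ± 60.0 CPM. CD27 of this list, chosen after its values were seen, was nearly absent from the KO libraries (1 count, against 758 counts and 18.3 ± 0.423 CPM in control, 1320-fold higher there with a 95% counting interval of 235 to 52000). In the list of IRF4 and its associated genes, 16 of 20 rose and 4 fell (median 0.43, adjusted p = 5.63e-07; adjusted p = 0.179 with an estimated correlation). This list shares 9 genes with the plasma cell list. By smallest p, the IRF4 list was led by CDK6 (log2 fold change 1.66, SE 0.03), SUB1 (1.08, SE 0.02), ELL2 (1.16, SE 0.03) and TNFRSF17, which encodes BCMA (1.09, SE 0.03). MYC targets followed (45 of 59 rose, 8 fell, median 0.61, mean 0.36, adjusted p = 4.88e-09; adjusted p = 0.155 with an estimated correlation). MYC itself was slightly lower. NPM1, a nucleolar member of this list, was 1837 ± 4.63 against 945 ± 9.74 CPM. By contrast, of 19 mature B cell genes 16 fell and 1 rose (median -1.67, adjusted p = 9.04e-11; adjusted p = 0.155 with an estimated correlation). Besides CD74, the B cell receptor subunit gene CD79A fell to 0.165 ± 0.0726 from 84.5 ± 2.34 CPM. The signalling genes BLNK (1.34 ± 0.166 against 62.7 ± 0.874 CPM) and BTK (7.93 ± 0.540 against 84.9 ± 0.726 CPM) fell as well.

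Immunoglobulin constant genes split. The kappa gene IGKC was 3310 ± 20.5 against 1488 ± 41.7 CPM and IGLC1 157 ± 1.27 against 75.5 ± 1.95 CPM, while IGHD had no counts in the KO libraries. This list's median was 0.74, with 4 of 8 members higher and 3 lower, but its mean and its test pointed down (adjusted p = 0.0188; adjusted p = 0.258 with an estimated correlation). The call was lost without KO replicate 2 (median 0.85, adjusted p = 0.0505), with the replicate block (adjusted p = 0.0823) and with no filter (adjusted p = 0.874, the largest over the alternatives). It was also lost with limma-voom and with thinned KO libraries (adjusted p = 0.657 and 0.567), where the test pointed up, as it did with no filter. The myeloma translocation and cyclin list had 9 of 13 genes higher and 3 lower (median 0.27, adjusted p = 0.00319; adjusted p = 0.233 with an estimated correlation). In it, CCND2 and the integrin gene ITGB7 (log2 fold change 1.39, SE 0.02) rose. CCND1, which encodes cyclin D1 (151 ± 1.12 against 538 ± 5.32 CPM), and TRAF3, a negative regulator of NF-kB signalling (37.6 ± 0.945 against 163 ± 6.11 CPM), fell.

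Inflammatory and stress signalling genes differed by pathway. Interferon response genes rose in 37 of 41 cases and fell in 1 (median 1.05, adjusted p = 1.52e-16; adjusted p = 0.155 with an estimated correlation). The antiviral gene MX2 was 73.2 ± 0.236 against 9.05 ± 0.304 CPM, and IFI6 was 202 ± 0.594 against 62.8 ± 0.544 CPM. Targets of p53 rose in 25 of 31 cases and fell in 5 (median 0.72, adjusted p = 4.63e-06; adjusted p = 0.155 with an estimated correlation). They included the cell cycle inhibitor gene CDKN1A (346 ± 0.132 against 145 ± 5.76 CPM) and MDM2 (2010 ± 21.4 against 1058 ± 36.5 CPM). NF-kB targets fell in 19 of 30 cases and rose in 6 (median -0.80, adjusted p = 1.98e-04; adjusted p = 0.258 with an estimated correlation). BIRC3 was 12.4 ± 0.190 against 84.2 ± 2.30 CPM, and RELB and NFKB1 each had a log2 fold change of -1.41.

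Markers of other cell types also differed, in both directions. Among fibroblast markers, 6 of 10 fell and 3 rose (median -3.68, or -3.0 with genes at 0 counts set to their bound; adjusted p = 0.00284; adjusted p = 0.189 with an estimated correlation). COL6A3 was 1.46 ± 0.308 against 293 ± 9.42 CPM, but COL1A1 only 0.334 ± 0.0513 against 9.85 ± 0.0426 CPM. This call was lost with no filter, with limma-voom and with thinned KO libraries (adjusted p = 0.0935, 0.271 and 0.214). Of 11 T and NK cell markers, 8 fell and 1 rose (median -2.05, adjusted p = 0.0375; adjusted p = 0.359 with an estimated correlation). ZAP70 was 0.209 ± 0.0664 against 30.3 ± 1.12 CPM and CD3E 13.9 ± 0.185 against 23.9 ± 0.665 CPM. The call was lost with upper-quartile factors (adjusted p = 0.0573) and without control replicate 2 (median -1.67, adjusted p = 0.06). Markers of epithelial and packaging cells (2 of 9 rose, 3 fell, median 0.10), myeloid cells (3 of 6 rose, 3 fell, median -1.32) and erythroid cells (1 of 5 rose, 2 fell, median -0.46) did not pass as lists by camera, with adjusted p of 0.103, 0.854 and 0.377, but did by fry. The camera test of the first pointed down and of the others up, against their medians. EPCAM and LIN28B of the first list had 0 counts in both KO libraries, while CDH2 was 40.7 ± 0.539 against 12.7 ± 0.627 CPM. Of the myeloid markers, CD68 was 57.0 ± 1.01 against 27.7 ± 2.37 CPM, CSF1R had 34 counts in the KO and 0 in the control libraries, and ITGAM was 0.0691 ± 0.0171 against 1.14 ± 0.229 CPM. Of the erythroid markers, HBA1 had 0 counts in the KO libraries and 3.85 ± 0.101 CPM in control, and the iron uptake receptor gene TFRC was 1011 ± 9.16 against 404 ± 4.23 CPM.

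**Figure D4:**
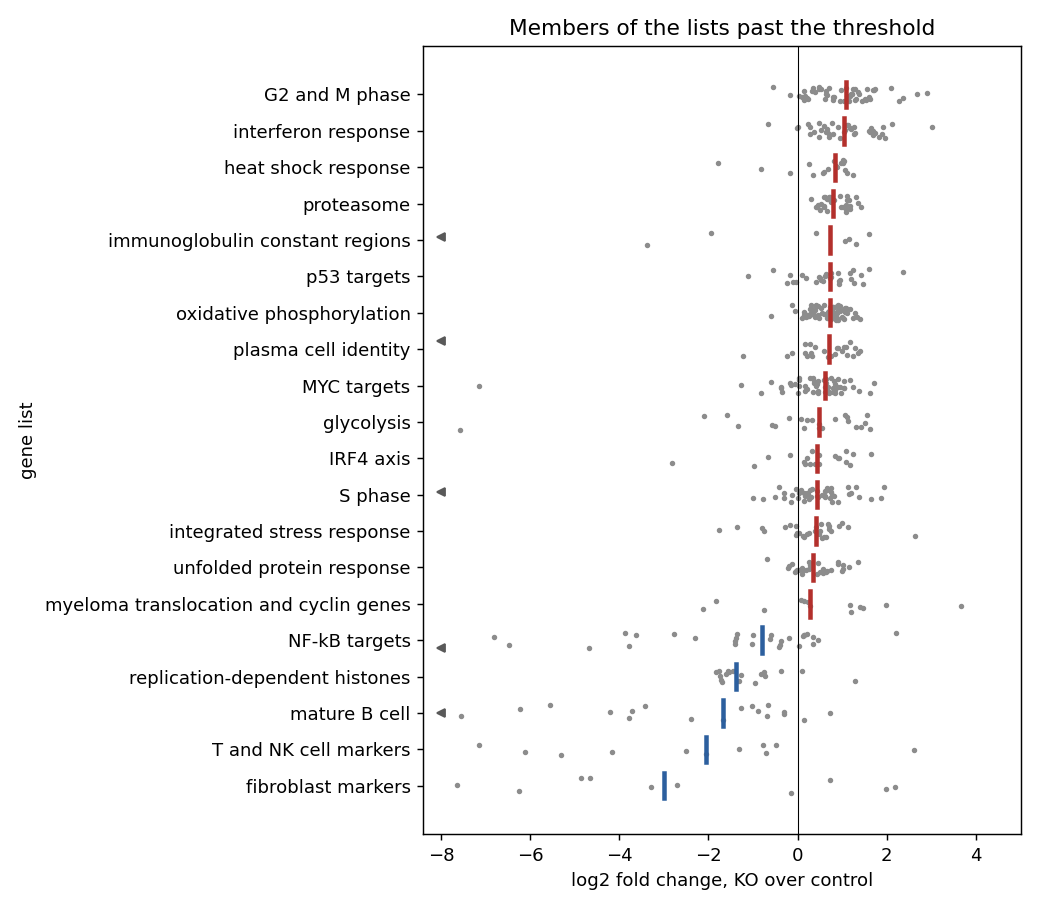
Log2 fold change (KO over control) of each member of the 20 lists past the threshold, ordered by median; dots are genes, bars are medians (red above 0, blue below). Triangles at the left edge are genes below -8, with genes at 0 counts in the KO libraries at their bound. The mature B cell median lies at -1.67, and the immunoglobulin list has a median of 0.74 although its test pointed down.

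Nor did the remaining lists pass by camera in the main fit. BAF complex subunits went both ways (11 of 28 rose, 14 fell, median -0.03, adjusted p = 0.573). Apart from BCL7A, the PBAF subunit gene PHF10 fell to 12.8 ± 0.422 from 59.2 ± 2.40 CPM and DPF3 rose to 76.0 ± 0.485 from 29.3 ± 0.302 CPM. The BCL2 family also divided (7 of 15 rose, 7 fell, median 0.03 with a mean of -0.16 and a test that pointed down, adjusted p = 0.319). Among its anti-apoptotic genes, BCL2 was 30.9 ± 0.558 against 379 ± 1.03 CPM and MCL1 2575 ± 30.2 against 1392 ± 22.1 CPM. Immediate early genes (15 of 31 rose, 11 fell, median 0.29, adjusted p = 0.0586) included DUSP6, a phosphatase of ERK, at 115 ± 1.58 against 26.2 ± 3.23 CPM. They passed by fry, and by camera with no filter and without control replicate 2 (adjusted p = 0.0291 and 0.0496). Ribosomal protein genes (48 of 78 rose, 19 fell, median 0.17, adjusted p = 0.0734) included RPL8, which fell to 669 ± 5.28 from 1230 ± 7.65 CPM, and RPL10, which rose to 2387 ± 2.58 from 1521 ± 37.4 CPM. This list passed upward with no filter, with limma-voom, without KO replicate 2 and without control replicate 2 (adjusted p = 1.72e-07, 0.00232, 0.0149 and 0.0095). Hypoxia response (8 of 19 rose, 9 fell, median -0.02 with a test that pointed up, adjusted p = 0.160), adhesion and migration (14 of 24 rose, 9 fell, median 0.54 with a mean below 0, adjusted p = 0.267) and fatty acid synthesis genes (9 of 14 rose, 5 fell, adjusted p = 0.301) did not pass. Neither did cholesterol synthesis (9 of 24 rose, 12 fell, adjusted p = 0.791), nuclear and small RNAs (5 of 13 rose, 6 fell, adjusted p = 0.670) or Polycomb and chromatin regulators (9 of 26 rose, 11 fell, adjusted p = 0.812). In the adhesion list, the chemokine receptor gene CCR2 fell to 0.193 ± 0.0716 from 204 ± 0.0736 CPM.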

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

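Thinning the KO libraries was the only alternative chosen after the data were seen. Counts of genes past the threshold stayed within 1.5 times of 13629, from 11169 with DESeq2 (which left 33255 genes without an adjusted p) to 14837 with no filter, and from 12363 to 13102 with 1 library left out, where the lone library is assumed to vary like the other group. The number changed at least 2-fold ran from 4328 to 7194, and the BCL7A log2 fold change from -5.28 to -5.06. Upper-quartile factors moved all genes by -0.13, and the share of calls that rose from 47.7% to 40.5%. The labels do not say that a replicate number is shared between groups, and same-numbered libraries did not deviate together (correlation 0.026 over 14957 genes); with the replicate number as a block, 13287 genes passed. With the KO libraries thinned, 12535 did. The number of lists past the threshold was 20, between 18 and 30 under all alternatives except an estimated inter-gene correlation, which left 0. That alternative moves no gene, and why the p-values rose was not tested. The fit has 2 residual degrees of freedom. A correlation above the preset 0.01 cannot explain every lost call. Heat shock and plasma cell genes had estimates of -0.046 and -0.012. Their camera p still rose from 4.73e-09 to 0.024 and from 3.15e-11 to 0.018. Other called lists had estimates above the preset, such as 0.129 for G2 and M phase genes. With the estimated correlation set aside, 366 list results kept direction and side of the threshold, 18 passed where they had not (10 of them with fry), 9 no longer passed and 10 reversed in the direction of the test. The reversals concerned the immunoglobulin list, with medians of -0.68 with no filter, 0.72 with limma-voom and 1.02 after thinning, none of them past the threshold, and 6 lists that had not passed. Their medians with no filter were 0.0494 (BAF subunits), -0.11 (BCL2 family), -0.10 (cholesterol synthesis), -0.89 (erythroid markers, and -0.64 with limma-voom), 0.0372 (nuclear and small RNAs) and 0.0578 (Polycomb and chromatin regulators); the cause was not tested. Of the named genes' results 1814 were the same, 1 was weaker (BCL7B with DESeq2) and 1 reversed: HBB, an erythroid marker not past the threshold (0.351 ± 0.228 against 0.481 ± 0.0212 CPM), had log2 fold changes of 0.10 without KO replicate 2 and -1.31 without KO replicate 1. At this depth, 0 counts in a group allow a level of up to 0.0416 CPM in the KO and 0.0723 CPM in the control group.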

Other observations

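Genes named here outside the rule were chosen after their values were seen. Zinc finger genes of chromosome 19, a set formed by name after the values were seen and not tested for enrichment, were mostly lower. Of 233 tested genes there with a ZNF name, 173 fell and 19 rose, with a median log2 fold change of -0.87. At the extreme, 22 were at least 10-fold higher in the control libraries, 9.44% against 3.13% of the 831 other protein-coding genes of that chromosome, whose median was 0.14. Many of these genes encode KRAB repressors, and they belong to clusters of related sequences that can share reads. The neighbours BIVM and KDELC1 on chromosome 13 both had 0 counts in the KO libraries and 29.9 ± 3.75 and 12.7 ± 1.34 CPM in the control libraries.

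Counts of the kappa variable gene IGKV3-15, the only one compared, were 0.109 and 0.105 of IGKC counts in the KO libraries and 0.107 and 0.113 in the control libraries. NCI-H929 is known as an IgA kappa line, yet the alpha constant genes were low in both groups: IGHA1 was 4.16 ± 0.00736 CPM in the KO and 1.67 ± 0.382 CPM in the control libraries, and IGHA2 1.05 ± 0.198 and 4.10 ± 1.01 CPM. The index and annotation used for counting are not given, so whether they produced the low alpha and high delta counts is not known. If all 4 libraries were counted with the same index, it would not by itself make IGHD differ between the groups. IGHD was at 0 CPM in the KO and 4682 CPM in the control libraries. Neighbours of MTCO1P12 in the same insertion of mitochondrial sequence on chromosome 1 did not share its difference, with log2 fold changes of 0.03 for MTND2P28 (adjusted p = 0.727) and 0.58 for MTATP6P1. The mitochondrial genes MT-ND2 and MT-ATP6 had log2 fold changes of -0.32 and 0.67. Whether reads of mitochondrial genes were assigned to these copies differently in the 2 groups was not tested.

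Of the tests below, the corrections for GC content and length and the comparison with neighbouring genes were set down before their results were seen, and the others afterwards. The one-sided absence of transcripts from the KO libraries was weighed first. Unequal depth argues the wrong way, because the silent genes were in the deeper libraries; after thinning, genes at least 10-fold higher in control still outnumbered the opposite by 52.9 to 1. Mature B cells mixed into the control libraries would bring HLA-DRA as well as CD74. HLA-DRA gained only 0.522% of the CPM that CD74 gained (1.38 against 264 CPM), and MS4A1 gained 0.907 CPM. That comparison covers only admixed cells that express HLA-DRA, and admixture of other cells was not tested. Loss of BCL7A within the 24 h of induction stays open. The half-life limit set for excluding it was so low that the test could hardly have done so. That it stays open therefore lends it no support. If transcription stopped when doxycycline was added, IGHD would need at least 16.8 halvings and so a half-life of at most 1.43 h. The 237 genes with 0 counts in both KO libraries would need a median of at least 6.06 halvings, a half-life of at most 3.96 h. A later stop would need shorter half-lives, and no half-life was measured here. Cells of the 2 groups that already differed before induction also stay open, untested.

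Neighbouring genes shifted together in blocks. After correction for GC content and length, 78.3% of the 23 outlying windows remained outside chance, which argues against these biases as the whole source. Medians of adjacent windows correlated at 0.604 over 189 pairs (permutation test, one-sided, p = 0.0001, the smallest that 10000 shuffles can give), while replicate contrasts had at most 1 outlying window. The blocks themselves prompted that test, so differences in copy number and regional effects of losing a chromatin remodelling subunit cannot be told apart here, because both follow the group and no DNA was measured. As a hypothesis, the libraries may come from sublines or cell lines that had diverged, or from a mislabelled culture. Admixture of cells other than mature B cells in the control libraries was not tested and stays open as well. DNA from the same cultures would be needed to decide.

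The rise of G2 and M phase, proteasome and oxidative phosphorylation genes was weighed last. The lowest of their 3 medians was 0.72 as measured, 0.82 after correction for GC content and length and 0.49 after subtracting the median of each gene's neighbours. Neither of these therefore accounts for the whole shift. With the KO libraries thinned it was 0.69, but thinning hardly changes ratios at the levels of these lists, so it cannot decide about depth. Subtracting the neighbours lowered the lowest median, but the genes that served as neighbours had a median of 0.20, so the drop does not measure the share of the blocks. Of 74 oxidative phosphorylation genes, 71 still lay above their neighbours. Loss of BCL7A and a prior difference between the cells both follow the group and stay open for these genes, untested.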
